A study of Mus musculus with 6 samples.

How the data were processed

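The values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects background, normalizes arrays to a common distribution and summarises the probes of a probe set, so differences between arrays in total signal are removed before any test. Total RNA was extracted with Trizol and RNeasy columns and biotin-labelled, per the labels' protocols. The deposited table holds 45101 probe sets in 6 arrays. Of these, 64 are manufacturer controls and were left out, which leaves 45037. No build is given in the sources used here.

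Gene names came from the platform annotation: 34945 probe sets have 1 gene symbol, 932 have several and 9160 are not named here. A GRCm38.p6 gene table served for names and for the order of neighbouring genes only. For gene lists each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Background limits a difference where a group lies below the overall median of 4.76, as in Osmr and Bcl3.

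Groups followed the sample titles. The labels name strain 129 for the wild type mice, and that of the mutant is not given in the sources used here. A difference in any gene, Prune2 and Lrrc2 included, can therefore come from alleles that differ between strains and not from the loss of Cdhr1. The labels number the arrays 1 to 3 in each group. Deviations of same-numbered arrays from their group means correlated at 0.477, 0.469 and 0.563 across probe sets, all above 0.1, and each of the 6 arrays correlated best with the array of its own number. The numbers were therefore taken to pair the arrays, a reading from the data, since the labels do not say what a number marks. Values with the replicate block are given where they change a call. Every SE printed is of the fit on group alone, also beside a call made with the block, unless marked. The pairs also serve as batches, each holding both groups.

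The test was limma (lmFit and eBayes, version 3.58.1, R 4.3.3) on group alone, with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 30 lists with at least 5 measured genes, beside camera with an estimated correlation and fry. With camera at the preset correlation 13 lists passed, and 0 did with an estimated correlation (5 at an unadjusted p under 0.05) or with fry's directional test (5). Of 656 list genes 62 had no named probe set. Within a list, members were also adjusted over the list alone, and "rose" or "fell" of a list member refers to that adjustment. Lists overlap: Osmr, Mt1, Mt2, Gfap, Clu, C1qa, C1qc, Atf3, Rgr, Rdh5 and Rpe65 are each in more than 1 list.

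Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Cdhr1, then up to 12 genes per direction among those past the threshold with non-overlapping groups, or up to 5 with the smallest p where fewer than 5 pass, then up to 4 members per list with the smallest p. Further names given with the replicate block were chosen after their values were seen. The alternatives were the replicate block, filters on dim probe sets, a further quantile normalization, median centring, eBayes with trend and robust fit, array weights, an ordinary t statistic, leaving out probe sets that can cross-hybridise, other thresholds and set tests, and leaving out each array.

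The steps were tested on simulated data with the real means and pair deviations, 200 changed probe sets among 45037 and 20 simulations per noise model. With noise at each probe set's moderated SD, group-only limma recovered 0.1% of log2 changes of 0.5, 54.4% of 1, 96.6% of 2 and 98.7% of 3, with 0.08% of its calls false. The blocked fit recovered 48.1%, 99.3%, 100% and 100%, but 14.8% of its calls were false, above the nominal level. After that result was seen, 2 further noise models were added: with 1 SD for all probe sets 4.55% of the blocked calls were false, and with variances drawn from the fitted prior 5.31%. Of changes of 0.5 the blocked fit recovered 95% under the first of these and 2.7% under the other, and of changes of 1 it recovered 100% and 85.5%. Which model is closest to the real noise was not settled, so the additional calls of the blocked fit are less certain than their adjusted p. Camera at the preset correlation gave an unadjusted p under 0.05 for a list of 25 genes raised by 0.5 in 20 of 20 simulations under each noise model. For a list of genes left unchanged it did so in 0 of 20, or in 1 of 20 with variances drawn from the fitted prior. These simulations had independent noise, so they do not test camera where list genes vary together. Figures were drawn with matplotlib 3.10.9.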

Results

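Retinal RNA of mice about 4 weeks old was measured on 6 single-colour Affymetrix arrays. There were 3 arrays of prCAD -/- mice, which lack photoreceptor cadherin, the product of the gene Cdhr1, and 3 arrays of wild type 129 mice. Each array held RNA from the pooled retinas of 3 mice, so the spread between arrays is a spread between pools. The comparison asks which retinal transcripts differ in a mouse that the submitters call a model of retinal degeneration. The arrays had medians between 4.74 and 4.79 on the log2 scale, and their number limits the precision of every value below.

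The Cdhr1 transcript was lower in all 3 mutant arrays. The 1 probe set named for Cdhr1 read 11.22 ± 0.21 (SD, n = 3) in wild type and 4.16 ± 0.20 (SD, n = 3) in mutant retina on the log2 scale. It fell by 7.06 (SE 0.15), which is 133-fold lower (limma, adjusted p = 2.18e-05). The differences within the pairs of same-numbered arrays were -7.38, -7.16 and -6.64. The mutant level lies below 4.76, the median over all probe sets, so background limits the fold, and where this probe set lies relative to the deleted part of the gene is not given in the sources used here.

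Besides Cdhr1, 4 probe sets passed the test over 45037 probe sets, all of them higher in mutant retina. A Prune2 probe set rose by 5.14 (SE 0.20, adjusted p = 8.51e-04), from 3.87 ± 0.20 to 9.01 ± 0.38 (SD, n = 3 each). Lrrc2, which encodes a leucine-rich repeat protein, rose by 1.60 (SE 0.11, adjusted p = 0.0150). Socs3, a feedback inhibitor of cytokine signalling through STAT3, rose by 1.55 at 1 of its probe sets (SE 0.10, adjusted p = 0.0150). Lad1, which encodes the basement membrane protein ladinin, rose by 1.26 (SE 0.09, adjusted p = 0.0269). The Prune2 and Socs3 probe sets are not the brightest of their genes and were singled out after their values were seen. Their wild type levels, 3.87 and 3.94, lie below the median of 4.76, so background limits these differences too. Of the other probe sets of Prune2, the brightest differed by -0.14 (SE 0.31), while those of Socs3 differed by 0.77 and 0.80.

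The next genes by p, each taken at its brightest probe set, did not pass over all probe sets. Agtpbp1 was 1.03 higher (adjusted p = 0.122), Osmr 1.77 higher (adjusted p = 0.160) and Antxr2 1.21 higher (adjusted p = 0.164). On the lower side, Snapc1 differed by -0.77 (adjusted p = 0.207), Spc25 by -3.09 (adjusted p = 0.297), Rbpms by -0.77 (adjusted p = 0.463) and Tnfaip3 by -0.61 (adjusted p = 0.479). With array weights Agtpbp1 (adjusted p = 0.0171), Osmr (0.0375), Snapc1 (0.0303), Spc25 (0.0397) and Cebpd (0.0303) passed over all probe sets, and Spc25 also without wild type replicate 3 (0.0382). With the replicate block 15 probe sets passed, 12 higher and 3 lower, and all 5 named above were among them. The 10 others included Antxr2 (adjusted p = 0.0379), Cebpd (adjusted p = 0.0379), Mt2 (adjusted p = 0.0227), a Gfap probe set (2.33 higher, adjusted p = 0.00598) and a Clta probe set (-2.29, adjusted p = 0.0154), these last 2 probe sets singled out after their values were seen.

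At an unadjusted p under 0.05 there were 1360 probe sets by the test on group alone and 3425 with the replicate block, below and above the 2251.8 that chance would give. Leaving out wild type replicate 1 or 2, or mutant replicate 1 or 2, left 2 probe sets, those of Cdhr1 and Prune2. Without wild type replicate 3 there were again 5, but Lrrc2 (adjusted p = 0.0814) and Lad1 (adjusted p = 0.110) were not among them. Without mutant replicate 3 there were 9, and without both arrays of replicate 3, a choice made after seeing the data, there were 16. In simulations the blocked fit gave 4.55% to 14.8% false calls, depending on how the noise was drawn.

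**Figure D1:**
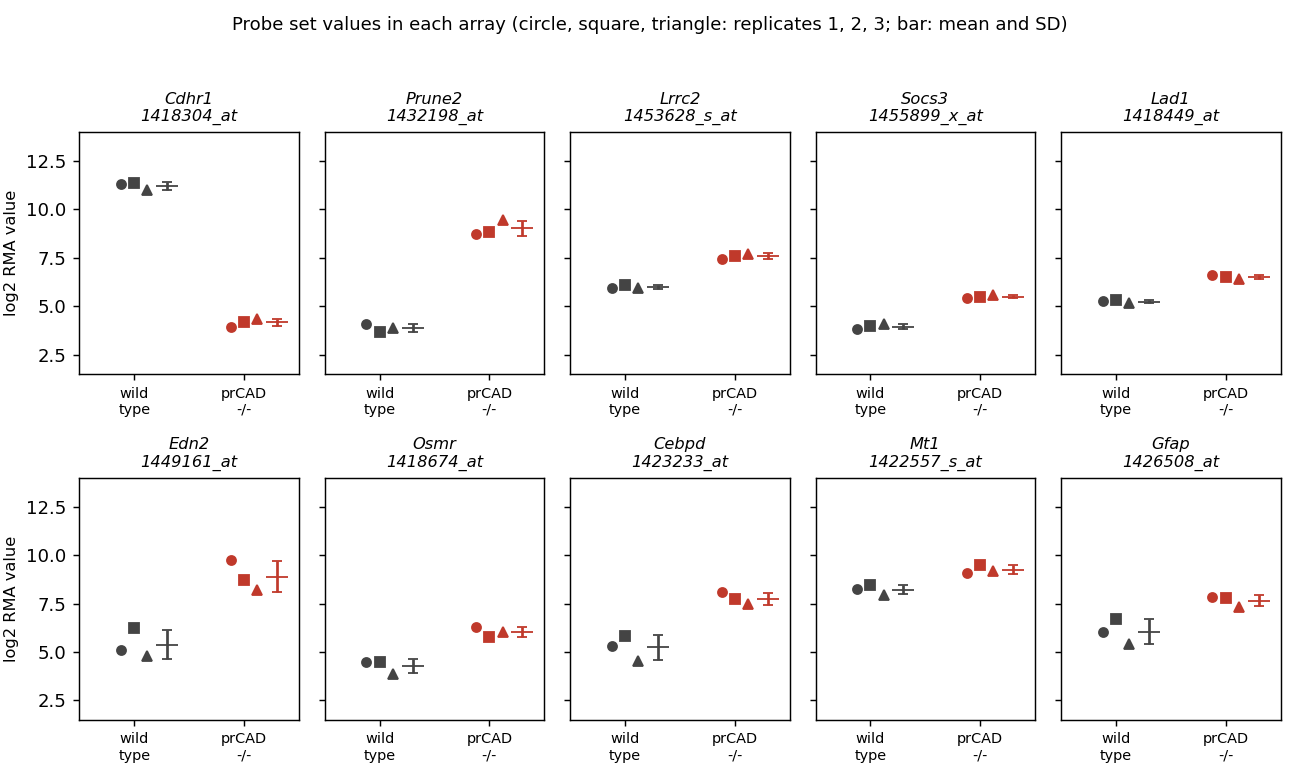
Log2 RMA values of 10 probe sets in each of the 6 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 arrays. The upper panels hold the 5 probe sets past the test over all probe sets, with Cdhr1 at 11.22 in wild type and 4.16 in mutant retina, and the lower panels hold members of the gliosis and cytokine lists, such as Edn2 at 5.38 and 8.89.

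Genes of reactive gliosis, the response of Müller cells and astrocytes to injury, were higher in mutant retina. Of 28 measured members, 12 rose and 0 fell when adjusted over the list alone, and 16 did not pass. None passed over all probe sets at its brightest probe set, though a dimmer Socs3 probe set did, as given above. Osmr, the oncostatin M receptor, rose by 1.77 (SE 0.20). Cebpd, a transcription factor of the acute phase response, rose by 2.52 (SE 0.32). Bcl3, a nuclear co-regulator of NF-kappaB, rose by 0.96 (SE 0.13), and Socs3 rose by 0.77 (SE 0.12) at its brightest probe set. The list had a median change of 0.62 (quartiles 0.12 and 1.03), and 0.60, 0.36 and 0.80 within the pairs. By camera the adjusted p was 1.16e-19, and adjusted p = 0.194 with an estimated correlation. Under the replicate block 16 members rose, and 2 of them, Cebpd and Mt2, passed over all probe sets at their brightest probe sets. Dimmer probe sets of Gfap (adjusted p = 0.00598) and Socs3 (adjusted p = 0.00863) passed with the block as well.

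In the endothelin, FGF and cytokine list, 2 of 24 members rose, adjusted over the list alone, and 0 over all probe sets. Edn2, which encodes endothelin 2, rose by 3.51 (SE 0.49), from 5.38 ± 0.76 to 8.89 ± 0.80 (SD, n = 3 each), and the other was Osmr, which the gliosis list also holds. Il6st, the shared receptor subunit of the interleukin 6 family, differed by 0.35 (SE 0.10), and Ngfr, the low-affinity neurotrophin receptor, by 0.51 (SE 0.17). The median change was 0.10, and 0.12, 0.10 and 0.20 within the pairs. By camera the adjusted p was 8.72e-05, and adjusted p = 0.216 with an estimated correlation. Il6st and Ngfr were among 5 members that rose with the replicate block, each at its brightest probe set. At its other probe sets Il6st differed by -0.09, 0.07 and 0.002.

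Markers of microglia and macrophages had a median change of 0.15, and 23 of 25 lay higher in mutant retina. Adjusted over the list alone, 3 rose, and over all probe sets 0. They were C1qc (0.47, SE 0.10) and C1qa (0.55, SE 0.13), subunits of the first complement component, and the lysosomal protease gene Ctss (0.85, SE 0.18). Csf1r, the receptor on which microglia depend, differed by 0.35 (SE 0.12). The pair medians were 0.24, 0.09 and 0.09. By camera the adjusted p was 1.06e-05, and adjusted p = 0.194 with an estimated correlation.

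Of 16 complement genes 5 rose, adjusted over the list alone, and 0 over all probe sets. Besides C1qc and C1qa, these were Cfi (0.36, SE 0.10), Serping1 (1.18, SE 0.34) and Clu (0.70, SE 0.22). The list's median change was 0.09 (pairs 0.17, 0.14 and 0.03), with a camera adjusted p of 4.27e-04, and adjusted p = 0.348 with an estimated correlation.

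Among 24 genes of the interferon response and antigen presentation 0 passed, adjusted over the list alone or over all probe sets, at a median change of 0.18 (pairs 0.23, 0.01 and 0.30). Ifitm3 differed by 1.21 (SE 0.39) and Ifit3 by 0.63 (SE 0.20). Camera gave an adjusted p of 3.95e-05, and adjusted p = 0.330 with an estimated correlation. Without mutant replicate 3 camera gave an adjusted p of 0.0533. Ifitm3, Bst2, Ifi35 and Irf9 rose with the replicate block.

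Rod photoreceptor markers were slightly lower as a list. The median change of 20 measured genes was -0.18, and 17 of them lay lower, while 0 passed adjusted over the list alone or over all probe sets. Esrrb, a nuclear receptor of rods, differed by -0.42 (SE 0.13), Mef2c by -0.69 (SE 0.23) and Reep6 by -0.42 (SE 0.16). Sag, which encodes rod arrestin, differed the other way, by 0.26 (SE 0.09). The pair medians were -0.11, -0.05 and -0.32. The rod list had a camera adjusted p of 1.29e-06, and adjusted p = 0.330 with an estimated correlation. Mef2c fell with the replicate block, adjusted over the list alone (adjusted p = 0.00381).

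In the cone list 2 of 16 members rose, adjusted over the list alone, and 0 over all probe sets. Pde6c, the catalytic subunit of the cone phosphodiesterase, rose by 0.76 (SE 0.12), and Gnb3, the beta subunit of cone transducin, rose by 0.99 (SE 0.21). The list's median change was -0.09 and its camera adjusted p 0.482. Opn1mw, the middle-wavelength cone opsin, differed by -0.31 (SE 0.15).

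Outer segment and connecting cilium genes had a median change of -0.04 over 32 measured members, of which 0 passed. Prph2, a structural protein of disc rims, differed by -0.73 (SE 0.37), and Rp1, a protein of the photoreceptor axoneme, by -0.19 (SE 0.10). Bbs4 differed the other way, by 0.28 (SE 0.15), and of all members 12 lay higher and 20 lower. Camera gave an adjusted p of 0.0603 without and 0.0489 with the replicate block, and adjusted p = 0.643 with an estimated correlation.

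In the photoreceptor synapse list 2 of 23 members rose, adjusted over the list alone, and 0 over all probe sets. They were Lrit1 (0.87, SE 0.17) and Lrit2 (1.08, SE 0.23), which encode leucine-rich repeat membrane proteins and lie directly beside Cdhr1 in GRCm38.p6 order. Rims2, an active zone protein, differed by -0.30 (SE 0.10). The list's median change was 0.05 and its camera adjusted p 0.258.

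**Figure D2:**
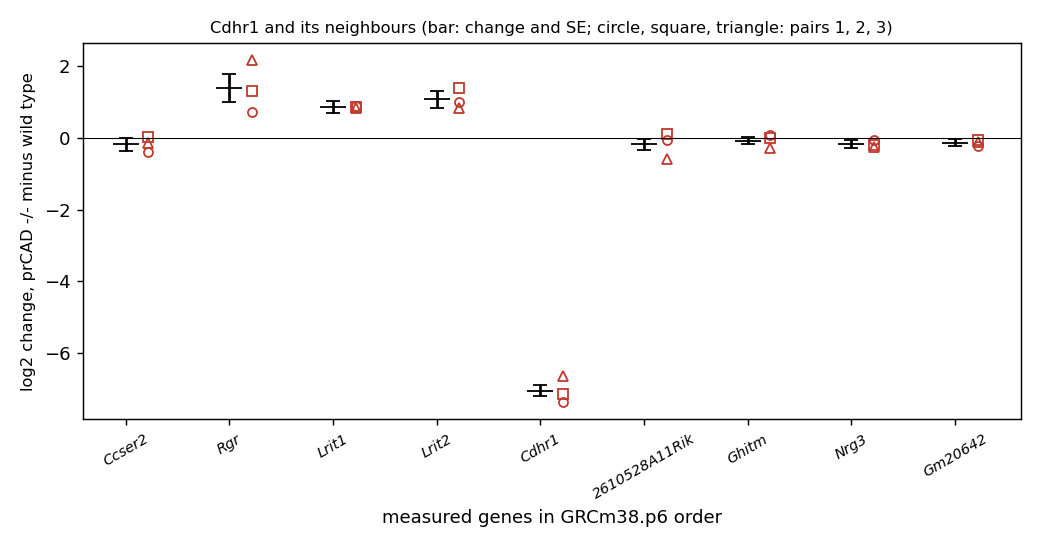
Log2 change, mutant minus wild type, of Cdhr1 and the 4 measured genes on each side of it in GRCm38.p6 order. Black bars give the change and its SE, and circles, squares and triangles the differences within pairs 1, 2 and 3. Rgr (1.40), Lrit1 (0.87) and Lrit2 (1.08) lie on one side of Cdhr1 (-7.06), and 2610528A11Rik (-0.18) and Ghitm (-0.07) on the other.

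Visual cycle genes, which recycle the retinoid chromophore, had a median change of 0.09 over 17 measured members, and 0 passed adjusted over the list alone or over all probe sets. The largest differences were of genes that the pigment epithelium list also holds: Rgr (1.40, SE 0.39), Rpe65 (1.07, SE 0.39) and Rdh5 (0.90, SE 0.28). These 3 rose with the replicate block. Rdh12, a dehydrogenase of photoreceptors, differed by -0.29 (SE 0.12). The visual cycle list had a camera adjusted p of 0.0407, and adjusted p = 0.330 with an estimated correlation. It was 0.111 without wild type replicate 2, 0.0790 without mutant replicate 2, 0.0922 without mutant replicate 3, 0.0679 with the strict dim filter and 0.0840 with the mean of all probe sets of a gene. The list's median in these settings ran from 0.07 with the mean of all probe sets to 0.19 without mutant replicate 3.

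Ganglion cell markers were lower, with a median change of -0.24 and 18 of 20 measured genes on the lower side. Rbpms, an RNA-binding protein of ganglion cells, fell by 0.77 (SE 0.12) when adjusted over the list alone, and 0 passed over all probe sets. Sncg, which encodes gamma-synuclein, differed by -0.36 (SE 0.10), Slc17a6, a vesicular glutamate transporter, by -0.48 (SE 0.17) and Vsnl1 by -0.33 (SE 0.16). The pair medians were -0.38, -0.20 and -0.09. The ganglion cell list had a camera adjusted p of 3.36e-08, and adjusted p = 0.216 with an estimated correlation. Rbpms, Sncg, Slc17a6 and Nefl fell with the replicate block.

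The other neuron lists did not pass. Bipolar cell markers had a median change of -0.02 (20 genes, camera adjusted p = 0.738), amacrine cell markers of -0.01 (22 genes, 0.738) and horizontal cell markers of -0.03 (12 genes, 0.671), and 0 of their members passed adjusted over the list alone. Trpm1, the channel of ON bipolar cells, differed by 0.59 (SE 0.15) at its brightest probe set, but by 0.16, 0.07 and 0.02 at its others. Th, the enzyme of dopamine synthesis in amacrine cells, differed by 0.24 (SE 0.09), and Tpm3 of the horizontal cell list by 0.32 (SE 0.10).

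The list of 24 Müller glia markers had a median change of 0.11 (camera adjusted p = 0.355). Spc25, a gene of the kinetochore complex, fell by 3.09 (SE 0.43), adjusted over the list alone, and 0 members passed over all probe sets. Clu differed by 0.70 (SE 0.22) and Cd9 by 0.56 (SE 0.18). With the replicate block 5 members rose, among them Clu and Cd9. The astrocyte and optic nerve list had a median change of 0.07 over 17 genes, of which Gfap, the glial intermediate filament gene, rose by 1.60 (SE 0.32), adjusted over the list alone. Dcn differed by 0.74 (SE 0.22). Gfap and Aldh1l1 rose with the replicate block. Camera gave an adjusted p of 0.0305, and adjusted p = 0.330 with an estimated correlation. Without single arrays it was 0.0627 (wild type replicate 1), 0.0917 (wild type replicate 3), 0.108 (mutant replicate 2) and 0.207 (mutant replicate 3), and without both replicate 3 arrays 0.296. With array weights and the block together it was 0.0686. The list's median ran from 0.03 to 0.11 without these single arrays.

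Markers of the retinal pigment epithelium, the layer behind the photoreceptors, were higher in mutant arrays. Of 23 measured genes 22 lay higher and 8 rose, adjusted over the list alone, while 0 passed over all probe sets. Among those that rose were the amino acid transporter gene Slc6a20a (0.92, SE 0.19), and Mlana (0.88, SE 0.21), Tyrp1 (0.68, SE 0.19) and Dct (1.00, SE 0.28), genes of pigment cells. The median change was 0.26, and 0.22, 0.28 and 0.56 within the pairs. The pigment epithelium list had a camera adjusted p of 1.27e-13, and adjusted p = 0.194 with an estimated correlation. The replicate block gave 11 members that rose, among them Ttr, Rpe65 and Stra6. Ttr, which encodes transthyretin, read 7.68 ± 1.76 in wild type and 9.95 ± 0.20 (SD, n = 3) in mutant arrays, and it was lowest in wild type replicate 3, an array that stood apart from the others.

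Lens genes differed mainly in the third pair of arrays, and the crystallins mainly through wild type replicate 3, which read low. The 13 crystallins had a median change of 0.72, but 0.08, 0.19 and 1.88 within the pairs, and 0 members passed. Cryaa, which encodes alpha A crystallin, differed by 0.43 (SE 0.25) and Crybb2 by 0.51 (SE 0.27). Camera gave an adjusted p of 3.95e-05, adjusted p = 0.497 with an estimated correlation, 0.0633 without wild type replicate 3, 0.0547 without mutant replicate 3 and 0.737 without both. The crystallin median was 0.21 without wild type replicate 3, 0.63 without mutant replicate 3 and 0.15 without both. The 12 other lens genes had a median change of 0.31, and -0.06, 0.20 and 0.70 within the pairs, and 0 passed, Mip differing by 0.81 (SE 0.56). Their camera adjusted p was 0.0194, adjusted p = 0.549 with an estimated correlation, and between 0.151 and 0.381 without wild type replicate 1, wild type replicate 3, mutant replicate 2 or mutant replicate 3, and 0.526 without both replicate 3 arrays. Caprin2 of this list rose with the replicate block.

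The remaining tissue lists did not pass. The blood list had a median change of 0.11 (9 genes, camera adjusted p = 0.166), the vascular and mural list of 0.09 (23 genes, 0.259, or 0.0323 without wild type replicate 2) and the ciliary body, iris and choroid list of -0.01 (14 genes, 0.533), and 0 of their members passed adjusted over the list alone. Hba-a2, a haemoglobin gene, differed by 0.26 (SE 0.15). With the replicate block Vwf of the vascular list (0.61, SE 0.16) and Cpxm2 of the ciliary body list (0.47, SE 0.17) rose.

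**Figure D3:**
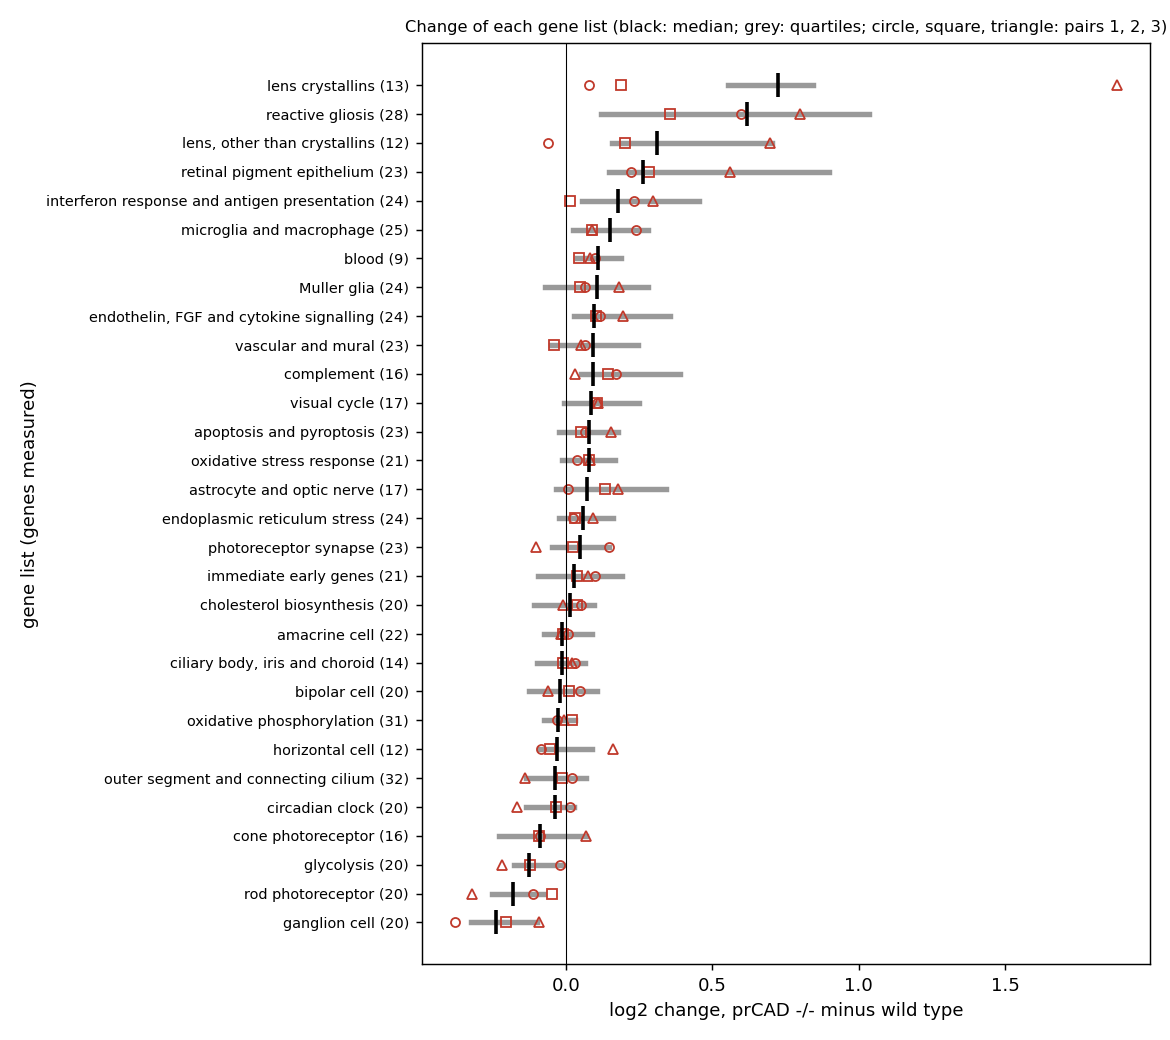
Log2 change, mutant minus wild type, of 30 gene lists, with the number of measured genes in brackets. Black marks are medians, grey bars the quartiles over genes, and circles, squares and triangles the medians within pairs 1, 2 and 3. Reactive gliosis has a median of 0.62 and 3 pair medians between 0.36 and 0.80, whereas the crystallin median of 0.72 comes with pair medians of 0.08, 0.19 and 1.88.

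Genes of glycolysis were slightly lower, with a median change of -0.13 over 20 genes and pair medians of -0.02, -0.12 and -0.22, and 0 passed. The lactate transporter genes Slc16a3 (-0.51, SE 0.19) and Slc16a1 (-0.41, SE 0.16) fell with the replicate block, while the hexokinase gene Hk1 differed by 0.29 (SE 0.10). Camera gave an adjusted p of 0.00210, and adjusted p = 0.497 with an estimated correlation, which was 0.310. It gave 0.0511 without mutant replicate 2, at a median of -0.07, and 0.0547 without mutant replicate 3, at a median of -0.03. Oxidative phosphorylation genes had a median change of -0.03 (31 genes, 0.141), and 0 passed, Cycs differing by -0.16 (SE 0.12). Cholesterol biosynthesis genes had a median of 0.02 (20 genes, 0.978), with a camera test in the lower direction, and 0 passed, though Pmvk (0.75, SE 0.23) rose with the replicate block.

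In the oxidative stress list the metallothionein genes Mt1 (1.02, SE 0.17) and Mt2 (1.31, SE 0.24) rose, adjusted over the list alone, 2 of 21 genes, and both also belong to the gliosis list. The other Mt1 probe set differed by only 0.007 (SE 0.35), at 5.08 in wild type and 5.09 in mutant retina. The oxidative stress list had a median change of 0.08 and a camera adjusted p of 0.0675, or 0.0327 with the replicate block, but 0.497 and, with the block, 0.398 with an estimated correlation. Gpx1 (0.32, SE 0.21, or 0.08 with the block) also rose with the block. Junb (0.85, SE 0.17) and Atf3 (0.56, SE 0.13), both transcription factors induced by stimulation or stress, rose among 21 immediate early genes, adjusted over the list alone. That list had a median change of 0.03 (camera adjusted p = 0.182), and with the replicate block Jun rose too. Circadian clock genes had a median change of -0.04 over 20 genes, of which 0 passed, Ciart differing by -0.40 (SE 0.18), at a camera adjusted p of 0.0643, or 0.0394 with the replicate block, but 0.549 and, with the block, 0.497 with an estimated correlation. Endoplasmic reticulum stress genes had a median of 0.06 (24 genes, 0.0643, or 0.00591 without mutant replicate 1), and 0 passed. That list also holds Atf3, which differed by 0.56 (SE 0.13) but did not pass there, while Calr differed by 0.20 (SE 0.11). Genes of apoptosis and pyroptosis had a median of 0.08 (23 genes, 0.141), and 0 passed. Tnfrsf1a of that list differed by 0.39 (SE 0.16) and Casp8 by 0.23 (SE 0.10).

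Control probe sets gave no difference in RNA quality that 6 arrays could show. The 3' minus 5' value of Actb was 0.69 ± 0.09 (SD, n = 3) in wild type and 0.82 ± 0.10 in mutant arrays (exact permutation test, two-sided, p = 0.2), and that of Gapdh was -0.15 ± 0.06 and -0.09 ± 0.15 (exact permutation p = 0.6), where 0.1 is the smallest p possible. The arrays differed by replicate number instead: the 5' probe set of 18S ribosomal RNA read 10.15 and 10.18 in the replicate 2 arrays and at most 5.68 in the others, and the bioB spike-in read 6.95 and 6.92 in the replicate 3 arrays and at least 8.22 in the others.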

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

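The alternatives without both arrays of replicate 3, array weights with the replicate block, and the blocked forms of the set tests were chosen after seeing the data. The 5 probe sets became 15 with the replicate block, 25 with array weights, 76 with both, 16 without both arrays of replicate 3, 3 with only the brightest 30% of probe sets, 3 without cross-hybridising probe sets, 2 at an adjusted p of 0.01 and 0 with the ordinary t statistic (1680 at an unadjusted p under 0.05), and 2 to 9 without single arrays. Both counts of 3 come from the filters themselves, of which the first left out the Lad1 and Socs3 probe sets and the other those of Lrrc2 and Socs3. The cause of the other changes was not tested. The Cdhr1 change stayed between -7.18 and -6.95 without single arrays, and at -7.06 it missed the threshold only with the ordinary t statistic (adjusted p = 0.0893). The 13 lists became 0 with an estimated correlation and 0 with fry's directional test, also with the block (0 and 0). Without single arrays they became 7 to 17, 7 being without mutant replicate 3. Fry's mixed test, which does not ask for 1 direction, gave adjusted p = 0.0119 for reactive gliosis and for microglia and macrophages. It gave adjusted p = 0.0141 for the endothelin, FGF and cytokine list and lay above 0.05 for the other lists. Apart from the calls named in the report, the block changed no other call of a list or named gene.

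No list passed the threshold in a setting where its median changed sign. With the sign kept, some lists gained the threshold. Without mutant replicate 1 these were outer segment (0.000895), oxidative stress (0.00190), endoplasmic reticulum stress (0.00591) and circadian (0.00865), without wild type replicate 2 outer segment (0.00740), circadian (0.0144), oxidative stress (0.0174) and vascular (0.0323), and without mutant replicate 2 oxidative phosphorylation (0.00219). With only the brightest 30% they were oxidative stress (0.0150) and circadian (0.0384), with array weights oxidative stress (0.0326, or 0.0239 with the block), without cross-hybridising probe sets outer segment (0.0284), with the mean of all probe sets outer segment (0.0396) and circadian (0.00373), and without both arrays of replicate 3 photoreceptor synapse (0.0415). Without single arrays the medians ran from -0.146 to 0.00930 (cone), -0.146 to 0.0481 (outer segment), -0.0270 to 0.108 (photoreceptor synapse), -0.0578 to 0.0786 (cholesterol), -0.0785 to 0.0256 (oxidative phosphorylation), -0.115 to 0.0395 (circadian), -0.0556 to 0.0249 (bipolar), -0.0323 to 0.0432 (amacrine), -0.0679 to 0.0763 (horizontal) and -0.0433 to 0.0452 (ciliary body). With array weights they were 0.0275 (oxidative phosphorylation), 0.0161 (amacrine, 0.0168 with the block too) and 0.000699 (horizontal). Dim filters gave 0.0258 (ciliary body), -0.12 (immediate early) and 0.0168 (bipolar), and probe sets without cross-hybridisation -0.00694 (cholesterol). Without both arrays of replicate 3 they were 0.00894 (circadian), 0.000137 (bipolar) and 0.0206 (amacrine), and with the mean of all probe sets 0.0136 (bipolar). The direction of the camera test differed in 40 cases, 0 of them past the threshold. By the sign of the median, 501 list results kept direction and side of the threshold, 20 gained it and 74 lost it. Other scalings moved the median change of all probe sets from 0.0106 to 0.00599 (quantile normalization) and 0.00729 (median centring). Of the results for named genes, 1991 kept their direction and side of the threshold, 32 gained it, 21 of these with array weights and the block together, 18 lost it and 0 changed direction.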

Other observations

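All tests in this part were chosen after the result was seen, except the counts of calls over other splits and the test of the window around Cdhr1, which were planned.

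Of the 10 ways to split the 6 arrays into 3 and 3, the real split gave 5 probe sets and the highest other 0, as 1 of 10 splits. It gave 13 gene lists by camera, while a split of wild type 1, wild type 3 and mutant 1 against the rest gave 15, so 2 of 10 splits gave as many. That split parts 1 pair, and among the 4 splits that part all 3 pairs the highest other gave 11. At an unadjusted p under 0.05 the real split gave 1360 probe sets. A split of wild type 1, mutant 1 and mutant 2 against the rest, which parts 1 pair, gave 5719, the most of any split. Among the 4 splits that part all 3 pairs the highest other gave 1029 probe sets. With 10 splits no share can fall under 0.05. The mean shift of the gliosis list was 0.685 in the real split and at most 0.409 in the others, that of the pigment epithelium list 0.546 and 0.384, and that of the endothelin, FGF and cytokine list 0.374 and 0.204. The rod list had 0.177 against 0.204 and the ganglion cell list 0.227 against 0.235, so another split shifted each of them further. The same held for the interferon list (0.2805 against 0.2998), visual cycle (0.2198 against 0.2433), glycolysis (0.104 against 0.171), crystallins (0.750 against 1.45) and the other lens genes (0.376 against 0.703). Groups did not overlap in 3511 probe sets, 7.80% of all, below the 10% that chance gives for unpaired arrays, with 2130 higher and 1381 lower in mutant arrays.

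Pigment epithelium markers were higher in mutant arrays. Of the 23 genes, 5 are in another list and 19 exceed the overall median in wild type retina, and in mutant arrays Ttr read 9.95 and Dct 8.58. A lower share of rods would raise the markers of other cells alike. The inner retinal neuron lists lay 0.601 below the pigment epithelium list (95% t interval over arrays 0.285 to 0.917, and within pairs 0.344 to 0.858). Since the pigment epithelium list was taken up because it was high, these intervals are no fair test of the difference. The bipolar, amacrine and horizontal cell lists had mean changes of 0.010, 0.017 and -0.012, so a rise of their markers was not seen. The ganglion cell list, also one of the inner retinal neuron lists compared, had a mean change of -0.227, which adds to the difference of 0.601. Tissue carried along in dissection may contribute: the list's correlation within groups, 0.188, lies at percentile 86.9 of 1000 random lists, above their median of 0.0736 and below the 95th percentile of 0.246, so carry-over and a change in the retina cannot be told apart. A biological difference between the genotypes stays open and untested.

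Rgr, Lrit1 and Lrit2 lie in a row beside Cdhr1 and were all higher in mutant arrays. Rgr is also a member of the pigment epithelium list, whose markers were higher too. Its pair differences were 0.71, 1.32 and 2.17, those of Lrit1 0.90, 0.86 and 0.85, and those of Lrit2 1.00, 1.40 and 0.84. Whether Rgr differs with its neighbours or with that list cannot be told apart here. Of 17988 runs of 3 neighbouring measured genes 0.00556% had a lowest t as high, which is this run alone. Since it was picked because it stood out, the share says nothing about chance. Alleles linked to Cdhr1 over 20 Mb may differ between the groups: the odds ratio of low p in that window, without these genes and Cdhr1, was 1.38 (95% interval 0.369 to 3.64, Fisher's exact p = 0.543), too wide to decide. In the planned window test the 1 gene that passed among 345 within 20 Mb was Cdhr1 itself, so that test says nothing about its neighbours. An effect of the altered locus on its neighbours was not tested.

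In some genes a single probe set differed while the brightest other probe set of the gene did not follow. Of these Prune2 passed the test over all probe sets, Clta only with the replicate block, and Phgdh (adjusted p = 0.248, or 0.0931 with the block) and Spc25 (0.297, or 0.0675) in neither. Against 5.14 in the Prune2 probe set, whose wild type level is below the overall median, stood -0.145 (SE 0.308), against -2.29 in Clta 0.0864 (SE 0.14), and against 2.34 in Phgdh 0.148 (SE 0.113), which argues against a change of the whole transcript level in these 3 genes. For Spc25 the value was -0.285 (SE 0.307), at a level too low to decide. A sequence difference under a probe or a change of 1 transcript form may account for such differences, and neither was tested.

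Wild type replicate 3 stood apart, with 122 probe sets more than 1 log2 unit above all other arrays and 78 below, against at most 53 in either direction for any other array. Ankrd33b read 9.17 there and at most 4.31 elsewhere, a Stx3 probe set 6.43 there and at least 10.29 elsewhere, and Arl2bp 4.29 there and at least 8.13 elsewhere. Eif2s3y, a Y-linked gene, read 1.95 in that array and 4.28 to 5.42 in the other arrays, while Xist read 10.63 in that array and 7.87 to 10.05 in the others, with 7.87 in mutant replicate 2. The value of 1.95 is the lowest of that array. In each pair the mutant array read higher for Eif2s3y, by 0.56, 0.89 and 2.33. It read lower for Xist, at 9.57 against 9.71, 7.87 against 10.05 and 9.79 against 10.63. The share of males may thus differ between pools and between the groups, which was not tested and cannot be told apart from genotype here.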
